A study of Enterobacter soli with 12 samples.

How the data were processed

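RNA of 12 cultures of Enterobacter soli LF7 was measured, 3 each of the wild type and the iacR deletion mutant with IAA or water. Per the labels' protocols, overnight cultures in rich broth, with 25 µg/ml chloramphenicol for the mutant, were washed and diluted into M9 minimal medium at 28 °C and 250 rpm, with succinate (12.5 mM) as carbon source beside casamino acids (0.2%) and iron sulfate (6.58 µM). IAA (200 µM) or water was added after 3 hours, and cells were stabilised 2 hours later. Per the labels' protocols, RNA was column-purified with a DNase step, ribosomal RNA was depleted, and single-end reads were taken on an Illumina HiSeq instrument.

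The authors deposited raw read counts per locus tag, per the file headers, as whole numbers for 4721 tags with 1 column per culture. The aligner, counting tool, strand setting, genome build and annotation are not given in the sources used here. The submitters' processing notes list edgeR and limma, with no role. Columns were matched to samples by their names through the series' design text, and 0 columns of values stayed unused. Of the tags, 109 are numbered with the letter R and 4612 are numbered without it. The file does not pair the tags with names or products, and no annotation was used here. Whether reads were counted by strand is not known, so reads of overlapping or antisense genes cannot be told apart, and R tags that agree within 10% in every library may share reads of copies.

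Counts were analysed with edgeR 4.0.16 in R 4.3.3. Tags with low counts were removed with filterByExpr, which left 4648 tags, libraries were scaled by TMM, and the quasi-likelihood model was fitted with robust estimation to all 12 libraries with 1 mean per group. Sharing the spread over groups gives more degrees of freedom, at the price that a noisy library affects comparisons it is not part of. Tags were called at a Benjamini-Hochberg adjusted p below 0.05. The 6 comparisons were IAA against water in each strain, mutant against wild type with water and with IAA, the difference of the IAA effects, and the mutant without IAA against the wild type with IAA. Standard errors are the log2 fold change divided by the square root of F. CPM use TMM-scaled library sizes. The biological coefficient of variation was 0.105.

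Total counts of 16961419 to 21733838 per library set the counting precision. Tested on simulated counts for the comparison of IAA with water in the wild type, with 200 of 4648 tags changed, the fit recovered 18.4% of 1.2-fold, 84.8% of 1.5-fold, 96.4% of 2-fold and 100% of 4-fold changes, with 5.43% false calls. For the difference of the IAA effects it recovered 2.4%, 53.2%, 90% and 99.6%, with 4.67% false calls. Each library was counted as a replicate, following its label. No 2 libraries of a group agreed within sampling noise, at a chi-square per tag of 3.18 to 189.5. This shows that no column of a group repeats another, but not that each library came from a separate culture.

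The rule for named tags, the tests and most alternative settings were fixed before the data were examined. The rule named the members of the iac gene list and iacR, members of other gene lists, and, per comparison, the 10 tags with the largest change in each direction among those with an adjusted p below 0.05, a mean count of at least 20 and no overlap between the groups; for the difference of the IAA effects the last condition was not used, and the last comparison was to name iac genes only. As the file has no gene names, neither the iac list nor any other gene list could be matched, and their tests were not run; the same holds for counts of the resistance cassette and of plasmid genes. At most 2 tags per direction are given as examples of a comparison; the bounds of the long run, Entas_2468, Entas_2484, Entas_2486 and the wild type values of Entas_4489 are printed beyond these. The long run, Entas_2484, Entas_2486, and the tags named outside it where the rule chose only its members were chosen after their values were seen.

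Neighbouring calls were counted in the order of the tag numbers and compared with 10000 shuffles of the calls over the numbered tags. Chance overlap was given by independent lists and by 40 simulated data sets with no effects, in which each tag was drawn on its own.

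Replicate numbers were checked for pairing by correlating the deviations of libraries from their group means. Of 18 pairs of the same number, 9 had a correlation over 0.1. The mutant pairs with water and IAA all did, at 0.396, 0.124 and 0.562, which meets the criterion for pairing set for the mutant's comparison of IAA with water. Libraries 1 and 2 were not told apart by number, however: mutant water library 1 correlated with mutant IAA library 2 at 0.482, and mutant water library 2 with mutant IAA library 1 at 0.216, so that library 3 alone stood with its own number. No label says what the numbers mark. The planned fit with the number as a block over all libraries gave 314 calls there against 296. Other alternatives were DESeq2 1.42.0, limma 3.58.1 (voom), median-ratio size factors, total counts, no filter, a filter of at least 5 CPM in at least 3 libraries, only the groups compared, no robust estimation, and leaving out each library. Alternatives chosen after seeing the data left out the long run, the R tags (in place of ribosomal RNA, which the file does not name) or both mutant libraries numbered 3, or set the block within each strain.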

Results

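RNA of the soil bacterium Enterobacter soli LF7, which degrades the plant hormone indole-3-acetic acid (IAA), was counted in 12 cultures. The cultures were of 2 strains, the wild type and a mutant in which the regulator gene iacR had been replaced by a chloramphenicol resistance cassette. Each strain received either 200 µM IAA or water, with 3 cultures in each of the 4 groups. Per the labels, expression of the iac genes, which encode IAA degradation, is inducible by IAA in the wild type and constitutive in the mutant. The total count per library lay between 16961419 and 21733838, and 4648 of 4721 locus tags were tested. The file does not pair the locus tags with gene names, so that tags are given by their identifiers and their number in the tag order. Precultures of the mutant held 25 µg/ml chloramphenicol and those of the wild type held none, so strain and antibiotic differed together in every comparison of the strains.

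The deletion was looked for first in the counts. Entas_2484 was the only tag with at least 100 counts in every wild type library and at most 3 in every mutant library, a criterion set after the values were seen. Its counts were 295, 241 and 204 in the wild type with water and 472, 387 and 359 in the wild type with IAA. In the mutant it had 0, 0 and 1 counts with water, and again 0, 0 and 1 with IAA. The summed counts gave a wild type to mutant ratio of 777 with water (95% exact interval 139 to 30720) and 1228 with IAA (220 to 48560), intervals that cover counting error only. The file does not say which tag is iacR. In the wild type Entas_2484 rose with IAA by a log2 fold change of 0.67 ± 0.11 (SE, 3 against 3 libraries; adjusted p = 0.00219, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

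The first comparison asked which transcripts IAA changed in the wild type. A run of 17 consecutively numbered tags, Entas_2467 to Entas_2483, rose together with a median 46.4-fold increase (range 3.55 to 61.4), and all 17 passed the test. This long run was defined after the data were seen, as the longest run of neighbouring tags called at least 2-fold higher. It took 0.00859 ± 0.00016% of the counts without IAA and 0.395 ± 0.041% with IAA (SD, n = 3 each). Entas_2478 had the largest increase of any tag chosen by the rule for named tags, from 3.73 ± 0.24 to 229.6 ± 10.1 CPM (counts scaled to the size of the library; SD, n = 3 each), and all 10 tags that the rule chose among those that rose lay in the long run. Outside it, Entas_2485 rose 4.36-fold, from 16.1 ± 0.18 to 70.3 ± 4.8 CPM; it was picked after its values were seen. Entas_3348 fell from 365 ± 18 to 118 ± 18.5 CPM and headed a run of 4 falling tags with a median 2.79-fold decrease. Entas_3987 fell from 449 ± 57 to 196.5 ± 39.9 CPM and headed another run of 4, with a median 2.15-fold decrease.

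In all, 322 tags changed with IAA in the wild type in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 214 higher and 108 lower, of which 37 rose and 7 fell at least 2-fold. Tags called higher were neighbours in the numbering in 82 pairs, and in 65 pairs without the long run, against a mean of 8.24 pairs without it over 10000 shuffles (one-sided permutation p = 1e-04, the smallest the shuffles can give). The shuffles treat neighbouring tags as independent, so noise shared by neighbours could also give more pairs. Tags called between the strains without IAA gave the same p in both directions, so it is not particular to IAA. The count fell to 180, 172 and 210 without wild type water library 1, 2 or 3, and to 210 and 194 without wild type IAA library 2 or 3. With the replicate number as a block within each strain, a fit chosen after the data were seen, it was 201. Scaled by total counts without TMM, the calls were 216 higher and 58 lower.

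**Figure D1:**
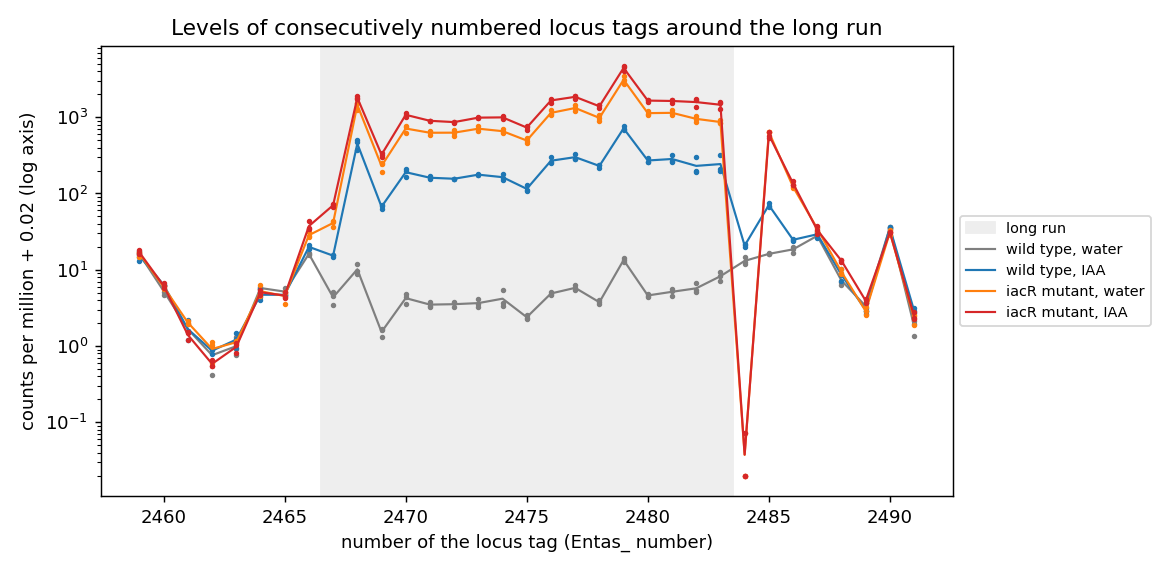
Levels of the locus tags around the long run (shaded), by tag number, in CPM on a log axis after adding a small constant so that 0 can be drawn; points are the 3 libraries of each group and lines join group means. The tags of the long run lie lowest in the wild type with water, higher in the wild type with IAA and highest in the mutant, while Entas_2484 drops to at most 1 count in each mutant library.

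The same addition was then compared with water in the mutant. The long run, already high without IAA, rose by a median of 1.43-fold, and 16 of its 17 tags passed the test; Entas_2468 had a 1.25-fold higher level (adjusted p = 0.181, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its share of the counts was 1.63 ± 0.15% with water and 2.46 ± 0.23% with IAA (SD, n = 3 each). Entas_0525 rose from 6.28 ± 0.56 to 24.9 ± 3.3 CPM, and Entas_4489 rose from 967.9 ± 39.9 to 3460 ± 232 CPM. Entas_3987 fell from 357 ± 29 to 180.8 ± 24.8 CPM, and the 4 tags of the run it heads all fell. Entas_0263 fell from 301 ± 38 to 147.6 ± 24.9 CPM (adjusted p = 0.0205, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), but its adjusted p was 0.077 without mutant water library 1, 0.0738 without mutant water library 3, 0.0909 and 0.054 without mutant IAA library 1 or 2, and 0.0615 without both mutant libraries numbered 3.

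In the mutant 296 tags changed with IAA in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 212 higher and 84 lower, of which 7 rose and 3 fell at least 2-fold. The count was 180 with only these 6 libraries in the fit and 173 with the replicate block within each strain. It was 163, 186 and 143 without mutant water library 1, 2 or 3, 190 and 180 without mutant IAA library 1 or 2, and 458 without mutant IAA library 3, when 222 were higher and 236 lower and 8 rose and 16 fell at least 2-fold. Both mutant libraries numbered 3 held 13 raised tags numbered with R, at 3.36% and 1.43% of scaled counts against 0.108 to 0.22% in the other libraries, and the count without both was 190. Scaled by total counts without TMM, the calls were 232 higher and 52 lower.

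Whether the IAA response was shared by the strains was asked of the calls in each. Both strains had 90 tags higher with IAA, where independent lists would share 9.76, and 22 lower, where they would share 1.95; 0 tags were called higher in the wild type and lower in the mutant, or the reverse, where independent lists would share 3.87 and 4.93. Entas_4489, which rose in the wild type from 952.5 ± 56.8 to 3465 ± 462 CPM (SD, n = 3 each), had log2 fold changes of 1.86 ± 0.10 in the wild type and 1.84 ± 0.10 in the mutant (SE). Without the long run 74 higher tags were shared, against 8.34 for independent lists. Across the 4628 tags left without the long run, Entas_2484, Entas_2485 and Entas_2486 (tags are not independent replicates), the log2 fold changes correlated with r = 0.19, while 40 simulations without any effect gave a mean of -0.014 and at most 0.139. The simulations drew each tag on its own and hold no noise that tags share. Deviations of real libraries of the same number correlated at -0.39 to 0.562 between groups. Such noise could move r past the simulated range, so r alone does not show a shared response.

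**Figure D2:**
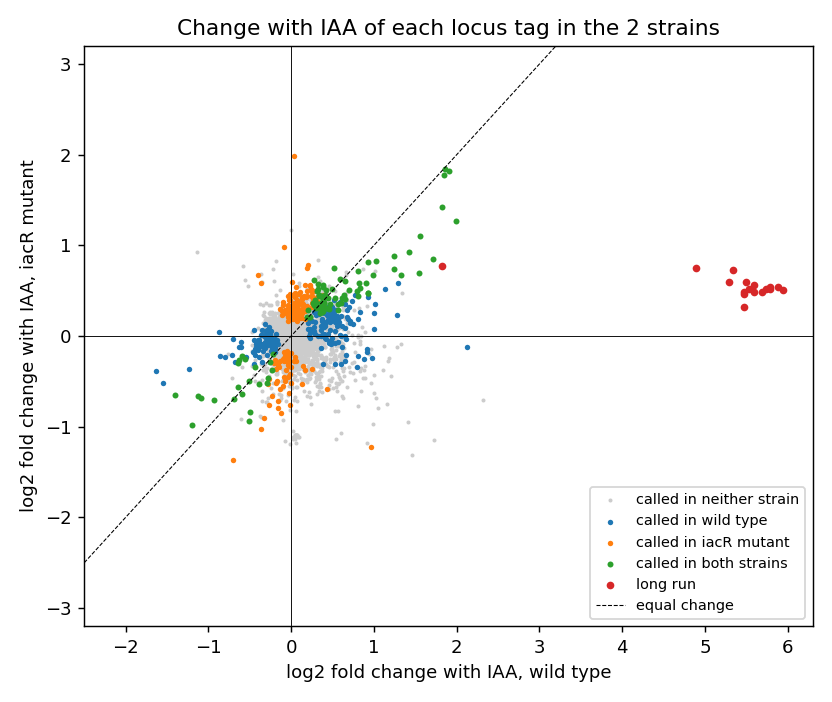
Log2 fold change with IAA in the wild type (horizontal) and in the iacR mutant (vertical), 1 point per tested locus tag, with colours for the strains in which it was called and a dashed line of equal change. The long run has a median log2 fold change of 5.54 in the wild type and 0.52 in the mutant, with Entas_2467 at 1.83 as its lowest in the wild type, and the tags called in both strains lie in the upper right and lower left.

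The difference of the IAA effects was itself tested. All 17 tags of the long run rose by a smaller factor in the mutant, with a median difference of -5.03 on the log2 scale (range -5.44 to -1.05). This holds for factors only. The run's share of the counts went from 0.00859 to 0.395% in the wild type and from 1.63 to 2.46% in the mutant. Entas_2485 also had a lower log2 change in the mutant, with a difference of -2.25 ± 0.10 (SE). Without IAA, Entas_3348 was already lower in the mutant, at a log2 fold change of -0.475 ± 0.13 (SE) against the wild type. With IAA it fell in the wild type and had a smaller, not significant decrease in the mutant (263 ± 24 to 201 ± 36 CPM; adjusted p = 0.108, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a difference of 1.25 ± 0.19. Entas_0525 went the other way, with 5.03 ± 0.16 and 5.11 ± 0.79 CPM in the wild type and a rise in the mutant, a difference of 1.95 ± 0.19. For Entas_4489 the difference was -0.03 ± 0.13 (adjusted p = 0.943, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

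The IAA effect differed between the strains for 48 tags in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 19 with a positive and 29 with a negative difference. The count was 26 and 29 without wild type water library 1 or 3, 29 without wild type IAA library 2, 28 without mutant water library 2, 30 and 29 without mutant IAA library 1 or 2, and 205 without mutant IAA library 3. It was 86 without both mutant libraries numbered 3, 30 with the replicate block within each strain, 105 with DESeq2, and 14 with the long run left out, where 31 of the 48 lay outside the run.

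**Figure D3:**
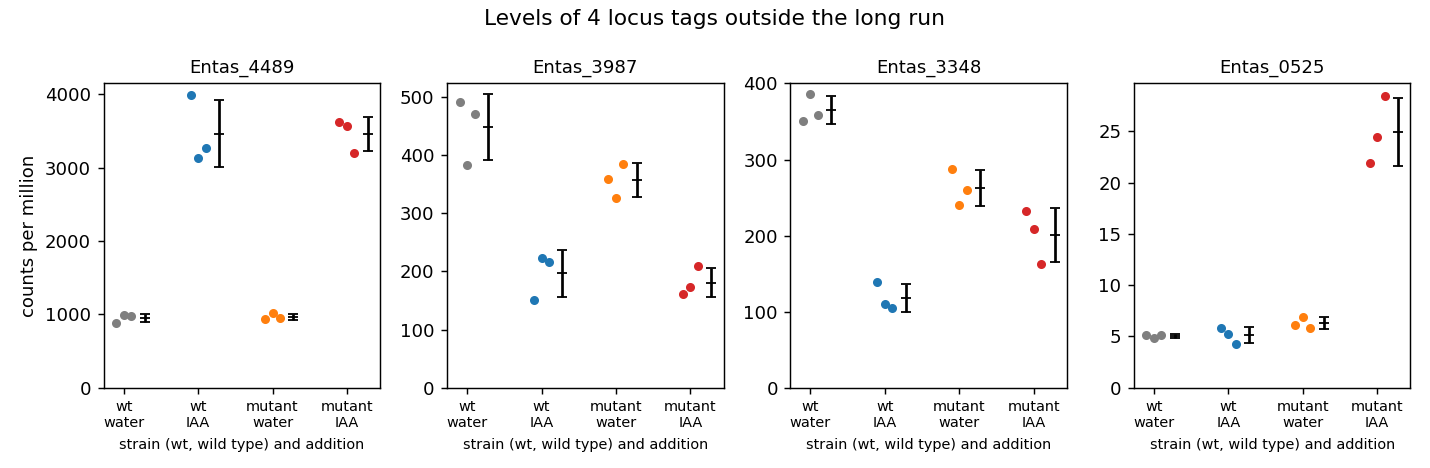
CPM of 4 locus tags outside the long run in each library (points) of the 4 groups, with the mean and SD of 3 libraries beside them. Entas_4489 rose and Entas_3987 fell with IAA in both strains, Entas_3348 fell with IAA in the wild type, and Entas_0525 rose with IAA in the mutant from 6.28 to 24.9 CPM.

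The strains were next compared without IAA, to see what the deletion changed in the absence of the inducer. All 17 tags of the long run were higher in the mutant, by a median of 180-fold (range 9.53 to 262). Entas_2478 had 979.9 ± 98.4 CPM in the mutant against 3.73 ± 0.24 in the wild type (SD, n = 3 each). Entas_2485 had 641 ± 6.4 CPM in the mutant against 16.1 ± 0.18, a 39.7-fold difference. The 2 tags that were at least 2-fold lower in the mutant were Entas_2484 and Entas_0291, the latter with 15.8 ± 3.0 CPM in the mutant against 33.9 ± 1.4.

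Without IAA 350 tags differed between the strains in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 151 higher and 199 lower in the mutant, and 38 of the higher ones differed at least 2-fold. The count was 133 and 155 without wild type water library 1 or 3, 202, 134 and 220 without mutant water library 1, 2 or 3, and 554 without mutant IAA library 3. That library is not part of this comparison and enters through the filter, scaling and spread shared by all libraries. It was 529 with DESeq2 and 582 with only these 6 libraries in the fit, and with the stricter filter on low counts 22 tags were higher and 3 lower by at least 2-fold.

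With IAA in both strains, the long run was still higher in the mutant, by a median of 5.99-fold (range 4 to 6.86), and all 17 tags passed. Entas_2485 had 588 ± 56 CPM in the mutant against 70.3 ± 4.8 (SD, n = 3 each). Entas_0263 was lower in the mutant with IAA, at 147.6 ± 24.9 against 420 ± 119 CPM. The difference between the strains covered 1125 tags in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 531 higher and 594 lower in the mutant, but 27 and 24 of them reached a 2-fold change. Of the tags called without IAA, 70 were again higher and 127 again lower, where independent lists would share 17.3 and 25.4.

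The count with IAA was 554 and 516 without wild type IAA library 2 or 3 and 500 and 611 without mutant IAA library 1 or 2, and 642 with only these 6 libraries in the fit. The 51 tags of at least 2-fold change became 81 without wild type IAA library 1, 33 without wild type IAA library 3, 83 without mutant IAA library 3 and 81 without both mutant libraries numbered 3. Scaled by total counts without TMM, 766 tags were higher and 378 lower, and the median tag moved to a log2 fold change of 0.102 from 0.003, so the balance of higher and lower calls depends on the scaling.

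The wild type response to IAA was set beside the effect of the deletion without IAA, 2 comparisons that share the wild type water libraries. Of the 214 tags that rose with IAA, 38 were also higher in the mutant, 21 of them outside the long run, where independent lists would share 6.95 and 5.7. Another 40 of the 214 were lower in the mutant, where independent lists would share 9.16. Of the 108 tags that fell with IAA, 15 were lower in the mutant, where 4.62 would be shared, and 2 were higher. The log2 fold changes correlated with r = 0.383 across the same 4628 tags. In 40 simulations without effects the shared libraries alone gave a mean of 0.515. Real effects change the spread of both sets of changes, so the lower r does not mean a relation weaker than chance. The covariance of the log2 fold changes was 0.0334 against a simulated 0.0144, a difference of 0.019. Noise that tags share, which the simulations lack, could also move this covariance. With 3 shared libraries the controls could not be split into parts of 2 libraries each, and part of the overlap in the same direction may come from them. The count of 53 tags shared in the same direction was 27, 30 and 35 without wild type water library 1, wild type water library 3 or mutant water library 2, and 33 with the long run left out, where 36 of the 53 lay outside it.

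Per the labels, iac expression is inducible in the wild type and constitutive in the mutant, and the mutant without IAA was therefore compared with the wild type with IAA, where strain and IAA differ together. As the iac genes could not be matched to tags, the long run was read here, and whether it holds them is not known. All 17 tags of the long run were higher in the mutant without IAA, by a median of 4.02-fold (range 2.68 to 4.41), with adjusted p of at most 7.68e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In this comparison 750 tags differed, 320 higher and 430 lower, and the count was 482 and 422 without wild type IAA library 2 or 3 and 451 and 497 without mutant water library 1 or 3.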

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

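The tests on Entas_2485 below were chosen after its values were seen; the relabelling of the libraries was chosen before the data were examined.

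For 4 named tags the IAA effect differed between the strains in the test of that difference, which is why they are listed here. The log2 effect in the mutant minus that in the wild type was -5.44 for Entas_2478, -2.25 for Entas_2485, 1.95 for Entas_0525 and 1.25 for Entas_3348. Of 100 relabellings of IAA and water within each strain, the real one included, 4 gave at least as many tags as the real 48, and the highest other relabelling gave 390. The 3 others that passed 48, with 390, 147 and 92 tags, put 0 of the 3 true IAA libraries of the wild type in its IAA group, so that the labels of the wild type were reversed and its IAA effect entered with the opposite sign. The relabellings thus do not hold the IAA effects equal, and this count does not say whether chance can be excluded for the 48 tags.

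Entas_2485 did not follow the long run near it, as without IAA in the mutant it stood at a log2 fold change of 3.19 ± 0.075 (SE) over the wild type with IAA, above the 1.42 to 2.14 of the long run's tags; transcription from the cassette would lift it there whatever else regulates it, so this leaves open whether both are regulated alike. In the mutant its log2 change with IAA was -0.125 ± 0.069, where 16 tags of the long run rose. The next tag, Entas_2486, looked at after its values were seen, was also higher in the mutant (6.62-fold without IAA, and a log2 fold change of 2.31 ± 0.067 over the wild type with IAA), with a log2 change with IAA there of 0.15 ± 0.061 (adjusted p = 0.172, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In the wild type, which has no cassette, Entas_2486 rose with IAA by a log2 fold change of 0.42 ± 0.072 (adjusted p = 0.00266, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A candidate explanation is transcription that reads out of the inserted cassette, if that cassette took the place of the neighbouring Entas_2484, but the deletion and the cassette never occur apart, so this and a biological effect of losing the regulator cannot be told apart. Without mutant IAA library 3 the decrease of Entas_2485 with IAA in the mutant passed the threshold, at -0.226 (adjusted p = 0.0394, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).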

How the results depend on the processing

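The fit with a replicate block within each strain and those leaving out the long run, the R tags or both mutant libraries numbered 3 were chosen after the data were seen. Leaving out 1 library, the counts of tags ranged from 172 to 457 for IAA in the wild type, 143 to 458 for IAA in the mutant, 133 to 554 between the strains without IAA, 500 to 1581 with IAA, 26 to 205 for the difference of the IAA effects, 422 to 1054 for the mutant without IAA against the wild type with IAA, 76 to 119 shared between the strains and 27 to 71 shared with the deletion. DESeq2 called 529 tags between the strains without IAA and 105 for the difference of IAA effects. With only the groups compared in the fit, the counts were 180 for IAA in the mutant, 582 between the strains without IAA and 642 with IAA. Without both mutant libraries numbered 3 they were 190 for IAA in the mutant and 86 for the difference. With the long run left out, the difference of IAA effects had 14 tags, where 31 of the 48 lay outside the run, and the overlap with the deletion 33, where 36 of the 53 did. The replicate block within each strain gave 201 for IAA in the wild type, 173 in the mutant and 30 for the difference, with fewer residual degrees of freedom; for the other moves, and the calls lost outside the run, the cause was not tested.

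The replicate block over all libraries gave 324, 314, 454, 1173, 52 and 816 tags for the 6 comparisons in the order above and shared 116 and 55, and moved no count by more than 1.5 times; outside the mutant's comparison of IAA with water the numbers are shared only as numbers. The other settings kept each total of called tags within 1.5 times, but not each direction: total counts without TMM took the lower calls from 108 to 58 and from 84 to 52 for IAA in the wild type and the mutant, and from 594 to 378 between the strains with IAA. Of the counts of tags changed at least 2-fold, 134 stayed within 1.5 times and 12 did not, 3 of these with the long run left out, 3 without both mutant libraries numbered 3, 1 with the stricter filter and 5 without 1 library. Of the named tags' values, 577 kept their direction and side of the threshold, 5 lost the threshold, all for Entas_0263 in the mutant, 1 passed it and 0 reversed. The planned removal of ribosomal RNA genes and the gene list tests were not run, since the file names no genes. Small changes were mostly missed: 1.2-fold changes were recovered in 18.4% of simulated cases for IAA in the wild type and in 2.4% for the difference. Depth, spread and number of libraries were not varied, so their parts in this cannot be told apart.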

Other observations

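The tests on the raised R tags, on the place of the lost tag and on neighbouring tags were chosen after the values were seen; those on tags outside the long run and on the size of the IAA response were chosen after the long run was found, but before their own results were seen.

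Runs of neighbouring tags moved together beyond the long run. In the wild type with IAA, 14 runs of at least 3 tags rose and 7 fell, holding 77 and 27 tags, the 77 including the 20 tags of the run that holds the long run. Between the strains with IAA, 40 runs held 212 lower tags, the longest of 22 tags, and 43 runs held 190 higher tags, 18 of them in the run that holds the long run. The run of 4 tags headed by Entas_3348 had a median log2 fold change of -1.48 with IAA in the wild type and -0.45 in the mutant, with a difference between the strains called for 3 of the 4. Without IAA all 4 were already called lower in the mutant than in the wild type, with a median log2 fold change of -0.64.

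Tags numbered with R stood apart in both mutant libraries numbered 3. Of 15 R tags that agreed within 10% with another in every library, 13 were higher there than in the other mutant libraries of their group, by a median of 16.8-fold with water and 9.6-fold with IAA, and of 3873 tags with a mean count of at least 100, 14 were over 4-fold higher in both, all 14 numbered with R and 13 of them among the similar tags. A rise of all R tags was argued against by the 53 other R tags, whose median log2 rise was 0.082 as the mean of both libraries (-0.108 with water and 0.277 with IAA, against 4.07 and 3.26 for the similar tags). Incomplete removal of ribosomal RNA may be the cause. The log2 rises of the 13 tags spanned a range of 0.53. Similar tags were chosen for agreeing within 10% in every library, however, so alike rises within such a set were given beforehand. In addition, 2 tags with a similar copy were not raised and what the tags are is not given, so this stays open. In the 6 comparisons 0 of the 13 were called by edgeR or by DESeq2, though at an unadjusted p below 0.05 all 13 passed in edgeR for the mutant without IAA against the wild type without or with IAA; no biological explanation was tested.

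Tags outside the long run differed between the strains without IAA, 333 of the 350 called. Leaving out the long run before scaling left 290 called, and leaving out the R tags left 354 against 350, with 282 and 327 of the original calls kept. The counts stayed within the bound of 1.5 times set for them. Leaving the tags out moved the log2 fold changes by a median of only 0.015 and 0.011, against 0.44 and 0.46 for the calls. Most calls thus remained without these tags, which argues against either share, acting through the scaling, as the cause of the calls kept. The calls that were lost stay open, as do the chloramphenicol of the mutant's precultures and the deletion, which were untested.

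The hypothesis that the rest of the IAA response was smaller in the mutant was tested on tags chosen by the mean of both IAA effects, without the long run and its neighbours. The slope of the mutant's log2 change on that of the wild type was taken as the geometric mean of both regression directions. It was 0.836 for 326 rising tags (95% bootstrap interval over tags, 0.766 to 0.922) and 0.855 for 190 falling tags (0.722 to 1.008). By these intervals the falling tags leave the hypothesis undecided. The 2 directions gave 0.685 and 1.019 for rising and 0.602 and 1.213 for falling tags, with plain averages of 0.852 (0.776 to 0.952) and 0.908 (0.763 to 1.075). A ratio of summed changes, which was not the measure set beforehand and was computed before it, was 0.901 (0.83 to 0.99) and 0.868 (0.745 to 0.992). A shift in scaling could not be excluded, with median differences of -0.014 (-0.047 to 0.024) in rising and 0.038 (-0.001 to 0.077) in falling tags. All these intervals resample tags, which are not independent replicates, and leave out the spread between cultures. The interval of the rising tags therefore cannot decide the hypothesis either.

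The hypothesis that the lost tag is the deleted regulator gene and the long run its target genes predicts that the lost tag lies beside the run. Entas_2484 lay at a distance of 1 in the numbering, where 2 flanking tags among 4595 numbered tags outside the run give a chance of 0.044%. This is consistent with the hypothesis, which was found and tested on the same data and which the file, without gene names, cannot settle.

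For each comparison of 3 against 3 libraries, 10 splits exist, too few for a share under 0.05. The real split was the 1 split with the most called tags in all 5, with 322 for IAA in the wild type, 296 for IAA in the mutant, 350 and 1125 between the strains without and with IAA, and 750 for the mutant without IAA against the wild type with IAA. The highest other split gave 0 tags in 4 of them and 430 between the strains with IAA, where it set wild type IAA library 1 and mutant IAA libraries 1 and 2 against the other 3. That split exchanges wild type IAA library 1 and mutant IAA library 3 between the strains, so strain differences also enter its calls. Both libraries stood apart in their groups. Their chi-square per tag against the others was 43.4 and 45.5 for the wild type library and 114.6 and 110.3 for the mutant library. Between the remaining libraries it was 3.18 in the wild type and 11.5 in the mutant. Mutant water library 3 stood apart too, at 132.4 and 189.5, against 79.6 between mutant water libraries 1 and 2. Both mutant libraries numbered 3 held the 13 raised R tags, whose part in these values was not measured. The split may thus point to a structure of the libraries, not only those with IAA, that the labels do not name.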
